A study of Mus musculus with 8 samples.

How the data were processed

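Bulk RNA was sequenced from 6 macrophage and 2 plasma cell samples of mouse bone marrow. Libraries were made with the SMART-Seq v4 Ultra Low Input kit, per the labels' protocols, a full-length method that does not mark the strand. The deposited values are whole-number read counts per gene, in a table of the 6 macrophage libraries and a table of the 2 plasma cell libraries. The submitters' processing notes name STAR, featureCounts, DESeq2 1.26 and the builds mm10 and GRCm38, without a role or order. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Each column was matched to a sample through its label, and 0 columns were left without a sample.

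Gene identifiers of the macrophage table were matched to GENCODE M21, an annotation of GRCm38. Of 47643 identifiers 47224 matched, and those without a match held at most 0.117% of a library's counts. The plasma cell table names genes by symbol, and 48081 of its 52458 entries were found in the same reference. Coordinates are from GENCODE M21, count from 1 and cover the whole gene, introns and untranslated regions included. Among transcripts of the mitochondrial genome, 5 genes had 0 counts in every macrophage library, so shares of mitochondrial counts are partial.

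Tests ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and other steps in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The designs, the gene lists and the rule for named genes were fixed before the data were examined. One edgeR quasi-likelihood model with a group term was fitted to the 6 macrophage libraries, with TMM scaling and genes kept by filterByExpr (minimum count 10, minimum total count 15), which left 15522 genes and 3 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. Adjusted p-values of genes in the text are from this test unless another tool is named, each log2 fold change is given with its standard error, and the groups hold 2 libraries each. All 3 pairs of groups were compared. The fit used the package's default estimate of the quasi-dispersion. This option had not been specified in advance, and both its settings were run before the default was kept, with 0, 34 and 0 calls by default and 22, 56 and 0 with bias-adjusted quasi-dispersions (TAM in contact over TAM not in contact, TAM in contact over naive, TAM not in contact over naive).

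The text names the genes of the study's cytokines and of the sort in every comparison. It also names up to 8 called genes per direction with the largest change, among those with a mean log2 CPM of 3 or more, no overlap between the groups' libraries and an assigned name, filled up by smallest p where fewer were called, and up to 4 members per list with the smallest p. The cytokine gene Il12b was left out after its counts of 0 and 1 in the naive libraries were seen. CPM values use the library's total count. A total of 45 gene lists of pathways, macrophage functions and other marrow cell types was fixed, with 699 distinct genes, and a gene can belong to several lists. Each of the 44 lists with at least 3 tested members was tested per comparison with camera on log2 CPM (prior count 2, preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists. Camera was repeated with the correlation estimated from the data, and fry was run beside it. Calls within a list are given over all genes and adjusted over the list alone. List medians are medians of the edgeR log2 fold changes. Overlaps between comparisons were set against independent lists and against simulated unchanged groups that share the same libraries. Principal components used log2 CPM of the 500 most variable genes.

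The scripts were tested on simulated counts of 14974 genes drawn from the real means and library sizes, with 200 genes changed. For TAM in contact over TAM not in contact edgeR recovered 42 of 100 genes changed by a log2 of 2 and 97 of 100 changed by 4, with 9 false calls, and DESeq2 73 and 99 with 94 false calls. For TAM in contact over naive edgeR recovered 43 and 99 with 15 false calls, and DESeq2 72 and 99 with 98 false calls. For TAM not in contact over naive, with nothing changed, edgeR called 0 genes and DESeq2 called 60 of the genes unchanged throughout and 2 of the others. A list with a planted change was called and 0 of 20 unchanged lists were. Simulated genes were drawn independently, so this does not test camera on correlated lists. In the data the estimated correlation within a list reached 0.92. Macrophage libraries held 28887725 to 46873056 counts, for which a count of 0 allows up to 3 counts, or 0.064 to 0.104 CPM. Shares of counts carry 95% Wilson intervals. Reads without molecular identifiers are not independent molecules, so these intervals and limits cover counting error only.

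Alternatives were DESeq2, limma-voom, RLE size factors, no filter or a stricter filter on low counts (at least 5 CPM in 2 libraries), fits on the 2 groups compared, removal of immunoglobulin and plasma cell genes, the mouse number of the TAM libraries as a block (no term for the naive libraries), another threshold, other gene numbers for principal components, and each macrophage library left out in turn. The plasma cell libraries entered no comparison of groups, because their shared label does not tell their origin apart. Their levels, and for a predicted profile their mean, were used in tests of explanations in the closing part, and CPM values of the tables were set side by side only as levels, since they were counted in separate tables.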

Results

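RNA was sequenced from 8 samples of mouse bone marrow. Vk*MYC myeloma, a transplantable mouse plasma cell tumour marked with green fluorescent protein (GFP), had been injected into the tibia of wild-type B6 mice. Tumour-associated macrophages (TAM) were sorted as F4/80 high and CD11b low, and divided by GFP into GFP-positive cells (TAM in contact with myeloma, n = 2) and GFP-negative cells (TAM not in contact, n = 2). Macrophages of naive mice formed the third group (n = 2), and 2 further samples held plasma cells. The total gene count was 41357964 and 31047348 in TAM not in contact, 44491870 and 42134293 in TAM in contact, 46873056 and 28887725 in naive macrophages, and 81792139 and 38343783 in plasma cells (replicates 1 and 2 in this order, here and below). Between 18296 and 20487 genes had at least 1 count in a macrophage library. The correlation of log2 CPM (counts scaled to the library total), across genes within a pair, was 0.967 for naive macrophages, 0.958 for TAM in contact and 0.844 for TAM not in contact. The labels number the TAM samples by mouse, and the naive samples are said to come from naive mice. How many animals gave each sample is not given in the sources used here, so p-values measure the spread between these samples.

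The genes of the cytokines in the study's title, interleukin 6 and tumour necrosis factor, passed edgeR's test in no comparison, while DESeq2 called both in the 2 comparisons that involve TAM not in contact. Tnf (ENSMUSG00000024401.14, GRCm38 chromosome 17, 35199381 to 35202007, minus strand) stood at 23.7 and 909 CPM in TAM not in contact, 27.0 and 66.4 in TAM in contact, and 15.6 and 17.2 in naive macrophages. Il6 (ENSMUSG00000025746.11, chromosome 5, 30013114 to 30019981, plus strand) stood at 1.76 and 27.1, 2.34 and 0.498, and 0.832 and 1.66 CPM in the same order. The Tnf log2 fold change was -3.26 ± 1.45 (SE, n = 2 per group, adjusted p = 0.321) for TAM in contact over TAM not in contact, 1.68 ± 1.37 (adjusted p = 0.589) over naive, and 4.94 ± 1.57 (adjusted p = 0.251) for TAM not in contact over naive. For Il6 these values were -3.32 ± 1.36 (adjusted p = 0.292), 0.33 ± 1.27 (adjusted p = 0.922) and 3.65 ± 1.38 (adjusted p = 0.304). DESeq2 gave Tnf an adjusted p of 0.0467 and Il6 0.0484 between the TAM groups, 0.00117 and 0.0345 for TAM not in contact over naive, and 0.462 and 0.932 for TAM in contact over naive. Adjusted over these 2 genes alone, both passed in edgeR for TAM not in contact over naive. Replicate 1 of TAM not in contact lay below or between the libraries of TAM in contact for both genes. The high values of both genes came from replicate 2 of TAM not in contact, in which 9.13% of counts fell on immunoglobulin genes. Without that library the Tnf value for TAM in contact over TAM not in contact turned to 0.95. The Il6 value over naive turned to -1.11 without TAM in contact replicate 1 and to -0.08 without naive replicate 1.

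**Figure D1:**
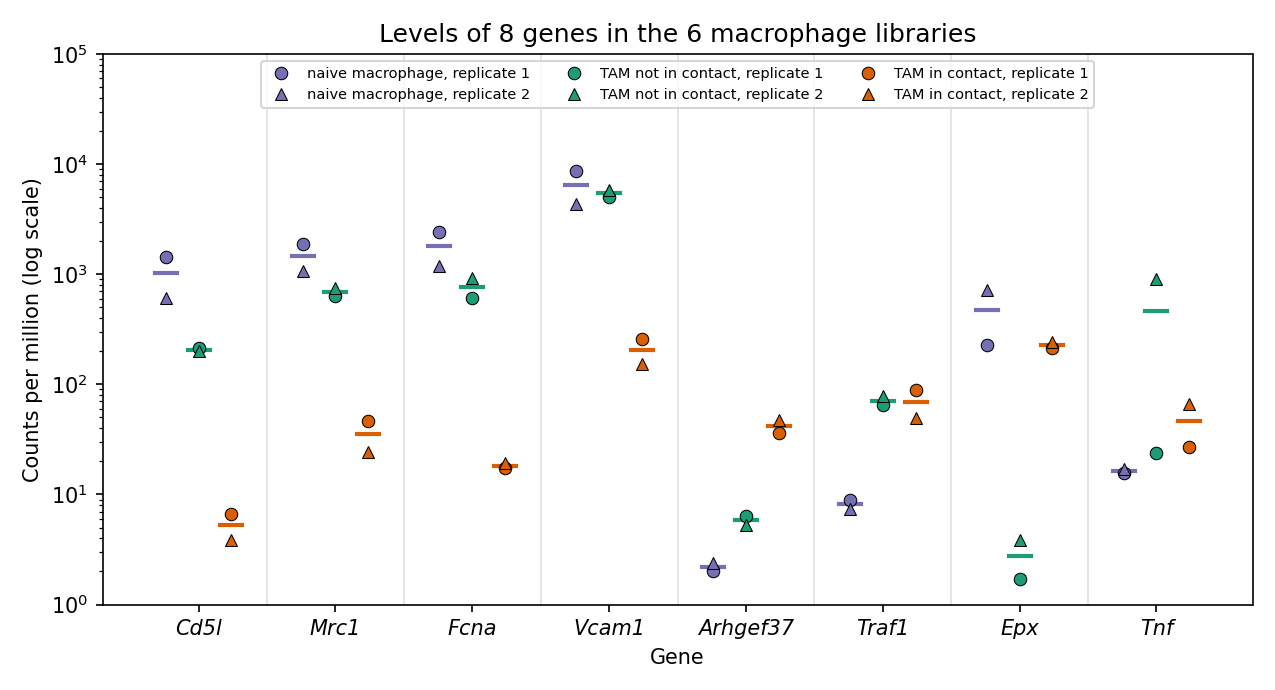
CPM (log axis) of 8 genes in the 6 macrophage libraries, with 1 point per library and a bar at the mean of each group of 2. Cd5l, Mrc1 and Fcna lie lowest in TAM in contact, Arhgef37 lies highest there, Epx is lowest in TAM not in contact, and Tnf reaches 909 in a single library of TAM not in contact.

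The first comparison asked how TAM that carried myeloma GFP differed from TAM that did not. Transcripts typical of resident bone marrow macrophages were at lower levels in TAM in contact. Cd5l, a secreted protein of tissue macrophages (ENSMUSG00000015854.7, chromosome 3, 87357881 to 87371073, plus strand), stood at 6.70 and 3.82 CPM against 213 and 200 (log2 fold change -5.29 ± 0.58 SE, n = 2 per group, adjusted p = 0.065). Epb41l3, which links the membrane to the cytoskeleton (chromosome 17, 69075683 to 69289989), had a value of -4.78 ± 0.44 (adjusted p = 0.065). The growth factor gene Igf1 had -4.53 ± 0.47 (adjusted p = 0.065), the adhesion molecule gene Vcam1 -4.71 ± 0.63 (adjusted p = 0.095) and the mannose receptor gene Mrc1 -4.27 ± 0.51 (adjusted p = 0.0772). None of these genes passed in edgeR's planned test, while DESeq2 called each of them. In the other direction, the eosinophil peroxidase gene Epx (ENSMUSG00000052234.2, chromosome 11, 87864000 to 87875536, minus strand) stood at 213 and 245 CPM in TAM in contact and 1.69 and 3.87 in TAM not in contact (6.40 ± 0.78, adjusted p = 0.0775).

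Among the 8 genes with the smallest p in each direction, those at lower levels in TAM in contact included the hormone receptor family gene Paqr9 (-4.99 ± 0.45), the sialyltransferase gene St6galnac2 (-5.66 ± 0.52), the growth factor gene Pdgfc (-4.96 ± 0.46), the lipid phosphatase gene Plpp3 (-5.20 ± 0.49), Pxdc1 (-4.18 ± 0.40), Gdpd1 (-4.42 ± 0.43) and the potassium channel gene Kcna2 (-5.63 ± 0.55). Those at higher levels included the lipoxygenase gene Alox15 (6.96 ± 0.78), Arhgef37 (2.86 ± 0.32), the receptor gene Gpr141 (2.31 ± 0.33), the prostacyclin receptor gene Ptgir (1.88 ± 0.27), Foxred2 (1.93 ± 0.27) and Card10 (2.44 ± 0.37). Their adjusted p-values lay between 0.065 and 0.112. Alox15, Foxred2 and Card10 also had negative values in TAM not in contact over naive. Their differences between the TAM groups need not be a gain in TAM in contact. Of the genes behind the sort, Adgre1 (F4/80) had -0.76 ± 0.51 (adjusted p = 0.489), Itgam (CD11b) 1.53 ± 0.28 (adjusted p = 0.135), Cd68 -0.77 ± 0.60 (adjusted p = 0.549) and Ptprc (CD45) 0.58 ± 0.50 (adjusted p = 0.59). The Cd68 value turned to 0.08 without TAM not in contact replicate 1.

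In edgeR's quasi-likelihood test 0 of 15522 genes passed an adjusted p of 0.05 between the TAM groups, with 2653 genes at an unadjusted p under 0.05. With the mouse number of the labels as a block it called 59 genes (7 higher and 52 lower in TAM in contact), among them Cd5l, Epb41l3, Igf1, Stab2, Plpp3, Alox15 and Epx. The sex-linked genes show that the libraries numbered mouse 2 are not from 1 animal. DESeq2 called 1619 genes (509 higher and 1110 lower in TAM in contact) and limma-voom called 0. With TAM not in contact replicate 1 left out, that group held replicate 2 alone and was assumed to vary like the others. Calls of that fit describe 1 library rather than the group.

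The gene lists fixed in advance were tested as sets with camera, and several of macrophage function lay lower in TAM in contact. Of 23 resident macrophage genes, 22 had negative values, with 0 called over all genes and 11 that fell adjusted over the list alone (median log2 fold change -2.64, adjusted p = 2.19e-11, but adjusted p = 0.569 with an estimated correlation). Iron and heme recycling followed, with 9 of 16 genes that fell adjusted over the list alone and 0 over all genes (median -1.10, adjusted p = 7.28e-06, and adjusted p = 0.569 with an estimated correlation). Its members included the iron exporter Slc40a1 (-3.63 ± 0.60) the biliverdin reductase gene Blvrb (-1.87 ± 0.36) and the heme-induced transcription factor gene Spic (-3.09 ± 0.64). In the lysosome list 6 of 30 genes fell adjusted over the list alone and 0 over all genes (median -0.91, adjusted p = 9.18e-06, and adjusted p = 0.588 with an estimated correlation), with cathepsin genes Ctsd at -2.69 ± 0.58 and Ctsl at -1.93 ± 0.36. The lysosome list had an adjusted p of 0.313 without TAM not in contact replicate 1. For efferocytosis, the uptake of dying cells, 6 of 19 genes fell adjusted over the list alone and 0 over all genes (median -0.79, adjusted p = 0.00136, and adjusted p = 0.569 with an estimated correlation). Its examples were the receptor genes Mertk (-3.89 ± 0.61), Stab2 (-5.19 ± 0.52) and Timd4 (-4.17 ± 0.67), and the bridging ligand gene Gas6 (-3.83 ± 0.62). This list had an adjusted p of 0.153 without TAM not in contact replicate 1. Lists of alternative activation, MHC class II presentation and Fc receptors were not called (adjusted p = 0.0633, 0.0837 and 0.941), and for Fc receptors the median was 0.25, the mean -0.04 and the test pointed up.

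Among lists of signalling and metabolism the values went both ways. In the interleukin 6 and STAT3 list 1 of 15 genes rose adjusted over the list alone and 0 over all genes (median 0.31, adjusted p = 0.033, but adjusted p = 0.569 with an estimated correlation). Its adjusted p was 0.301 and 0.0821 without TAM not in contact replicate 1 and 2, 0.0874 without TAM in contact replicate 2, and 0.0636 and 0.0642 without naive replicate 1 and 2. In the glycolysis and hypoxia list 0 of 22 genes passed over all genes or adjusted over the list alone (median 0.47, adjusted p = 0.0153, and adjusted p = 0.569 with an estimated correlation), and without TAM not in contact replicate 2 the adjusted p was 0.0591. MYC targets and ribosome biogenesis lay lower, with 0 of 22 genes that passed over all genes or adjusted over the list alone (median -0.35, adjusted p = 0.00953, and adjusted p = 0.588 with an estimated correlation). The adjusted p of that list was 0.133 without TAM not in contact replicate 1 and 0.0755 without TAM in contact replicate 2. The tumour necrosis factor and NF-kB response was not called (median -0.31, adjusted p = 0.128).

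Markers of other marrow cells moved with the same contrast. In the list of eosinophils, basophils and mast cells 9 of 16 genes rose and 1 fell adjusted over the list alone, with 0 over all genes (median 2.24, adjusted p = 7.28e-06, and adjusted p = 0.569 with an estimated correlation). The granule protein gene Prg2 had 5.08 ± 0.76 and the ribonuclease gene Ear1 6.96 ± 1.07, while the member that fell was the eotaxin receptor gene Ccr3 (-4.15 ± 0.72). In the neutrophil list 5 of 17 genes rose adjusted over the list alone and 0 over all genes (median 1.41, adjusted p = 1.56e-05, and adjusted p = 0.569 with an estimated correlation), with S100a8 at 1.93 ± 0.57 and the cathelicidin gene Camp at 1.90 ± 0.50. In the monocyte list 5 of 14 genes rose adjusted over the list alone and 0 over all genes (median 1.32, adjusted p = 0.000352, and adjusted p = 0.569 with an estimated correlation), with the chemokine receptor gene Ccr2 at 2.66 ± 0.66 and the CD43 gene Spn at 1.69 ± 0.45. Megakaryocyte and platelet genes lay on the other side, where 9 of 15 fell adjusted over the list alone and 0 over all genes (median -2.16, adjusted p = 3.34e-06, and adjusted p = 0.569 with an estimated correlation). The platelet chemokine genes Ppbp and Pf4 had -6.67 ± 1.04 and -2.07 ± 0.41. Over naive, the medians of the eosinophil and neutrophil lists were -0.79 and -0.68 in TAM in contact. In TAM not in contact they were -3.54 and -1.95. Neither median lay above naive in TAM in contact. For the monocyte list the medians over naive were 2.32 in TAM in contact and 0.30 in TAM not in contact.

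Stress, cytokine and mitochondrial lists lay lower in TAM in contact, with the highest levels in replicate 2 of TAM not in contact. Without that library the cytokine list lost its call and the other 2 kept theirs. Of 22 genes of the unfolded protein response, all had negative values and 0 passed over all genes or adjusted over the list alone (median -1.08, adjusted p = 1.61e-05, and adjusted p = 0.569 with an estimated correlation). Among them Creld2 stood at 118 and 503 CPM in TAM not in contact and 61.4 and 49.0 in TAM in contact, and the secreted stress protein gene Manf had -1.03 ± 0.27. Creld2, Xbp1 and Edem1 are also on the plasma cell marker list, which lay lower as well (median -2.30, adjusted p = 3.34e-06, and adjusted p = 0.569 with an estimated correlation), and replicate 2 of TAM not in contact is the library with 9.13% immunoglobulin counts. Of 17 inflammatory cytokine genes, 2 fell adjusted over the list alone and 0 over all genes (median -2.13, adjusted p = 0.0141, and adjusted p = 0.612 with an estimated correlation), and without that library the adjusted p was 0.362. Without TAM in contact replicate 2 it was 0.0596. The interleukin gene Il1a stood at 50.5 and 660 CPM in TAM not in contact and 3.55 and 2.16 in TAM in contact, and Il23a, of the interleukin 23 subunit, at 0.339 and 47.4 against 0.067 and 0.095. All 7 measured transcripts of the mitochondrial genome fell adjusted over the list alone, with 0 over all genes (median -1.80, adjusted p = 3.92e-05, and adjusted p = 0.569 with an estimated correlation). Their summed share was 0.353% and 0.876% of counts in TAM not in contact and 0.142% and 0.18% in TAM in contact. In all, camera called 19 of 44 lists, 6 higher and 13 lower in TAM in contact. With an estimated correlation it called 0, and fry, which asks whether a list's genes move on balance 1 way, called 1 (matrix and adhesion, adjusted p = 0.0454).

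The second comparison set TAM in contact against macrophages of naive mice. The genes that passed were mostly lower in TAM in contact and included several of resident macrophages. Cd5l fell from 1435 and 614 CPM in naive macrophages to 6.70 and 3.82 (log2 fold change -7.46 ± 0.65 SE, n = 2 per group, adjusted p = 0.0425). Fcna, which encodes the lectin ficolin A of the complement system (ENSMUSG00000026938.10, chromosome 2, 25624666 to 25628030, minus strand), fell from 2426 and 1176 CPM to 17.3 and 19.3 (-6.46 ± 0.58, adjusted p = 0.0425). Mrc1 (ENSMUSG00000026712.3, chromosome 2, 14229392 to 14332057, plus strand) fell from 1865 and 1080 CPM to 46.7 and 24.5 (-5.22 ± 0.54, adjusted p = 0.0442). Arhgef37 (ENSMUSG00000045094.7, chromosome 18, 61491657 to 61536594, minus strand), rose from 2.00 and 2.39 CPM to 36.3 and 47.0 (4.41 ± 0.35, adjusted p = 0.0425).

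In all, edgeR called 34 of 15522 genes, 29 lower and 5 higher in TAM in contact, with adjusted p-values from 0.0425 to 0.0493. The largest negative value belonged to Gfra4, a receptor of the glial cell-derived neurotrophic factor family (chromosome 2, 131039632 to 131043088), at -8.31 ± 0.66. It fell from 43.8 and 31.9 CPM to 0.112 and 0.095. Its family member Gfra2 (-6.12 ± 0.53), Vstm4 (-6.90 ± 0.68), the transcription factor gene Klf15 (-6.76 ± 0.67), St6galnac2 (-6.57 ± 0.54) the calcium-binding protein gene Chp2 (-6.28 ± 0.61), Stab2 (-5.55 ± 0.53) and Igf1 (-4.91 ± 0.48) also fell. The genes that rose, besides Arhgef37, were Traf1, an adaptor of tumour necrosis factor receptors and a target of NF-kB (chromosome 2, 34941750 to 34961772), at 3.22 ± 0.35, the G protein-coupled receptor gene Gpr132 (chromosome 12, 112850873 to 112868228) at 3.14 ± 0.31, the small GTPase gene Arl5c at 2.71 ± 0.28, and Gm6377, an unnamed gene model outside the naming rule that was added after its values were seen, at 4.64 ± 0.47. Nupr1 (4.21 ± 0.49, adjusted p = 0.0529), Plxdc1 (2.17 ± 0.27, adjusted p = 0.0648), Ptpro (3.21 ± 0.42, adjusted p = 0.0692) and Gch1 (2.19 ± 0.29, adjusted p = 0.0721) did not pass. For 16 of the 34, Fcna, Gfra4 and Mrc1 among them, the annotation places another gene over the locus, and counting from an unstranded kit cannot fully separate such pairs.

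Each of these 34 calls depended on all 4 libraries compared. Without either library of TAM in contact or either library of naive macrophages edgeR called 0 genes, with 1596, 941, 865 and 1096 genes at an unadjusted p under 0.05 (TAM in contact replicates 1 and 2, naive replicates 1 and 2 left out). No other tool was run on these smaller sets. Leaving out such a library also leaves its group with 1. A fit on the 4 libraries alone called 664 genes (216 higher and 448 lower in TAM in contact) and kept all 34 calls. Without TAM not in contact replicate 1 or 2, which enter through the shared spread, the gene filter and the scaling, the called genes kept their calls. These fits tested 17041 and 16467 genes, against 15522. With the mouse number as a block edgeR called 187 genes (68 higher and 119 lower), which added Nupr1, Plxdc1, Ptpro, Gch1, Timd4 and Socs3. That block joins libraries numbered mouse 2 that are not from 1 animal. On all 6 libraries 2270 genes had an unadjusted p under 0.05, DESeq2 called 1230 genes (476 higher and 754 lower) and limma-voom called 0. Of the genes behind the sort, Adgre1 had -0.53 ± 0.51 (adjusted p = 0.654), Itgam -0.21 ± 0.27 (adjusted p = 0.753), Cd68 -0.09 ± 0.59 (adjusted p = 0.956) and Ptprc 1.17 ± 0.50 (adjusted p = 0.357). Adgre1 turned to 0.04 without naive replicate 1 and Itgam to 0.03 without naive replicate 2.

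By list, resident macrophage genes were lower than in naive macrophages, with 3 of 23 that fell over all genes and 13 adjusted over the list alone (median -2.58, adjusted p = 2.83e-10, but adjusted p = 0.533 with an estimated correlation). The 3 were Cd5l, Mrc1 and Epb41l3 (-4.40 ± 0.43), and Timd4 had -6.19 ± 0.74 (adjusted p = 0.0544). In iron and heme recycling 10 of 16 genes fell adjusted over the list alone and 0 over all genes (median -1.65, adjusted p = 1.71e-06, and adjusted p = 0.533 with an estimated correlation), with Slc40a1 at -4.37 ± 0.62 and the biliverdin reductase gene Blvrb at -2.51 ± 0.37. Among erythroid genes 1 of 19 fell over all genes and 5 adjusted over the list alone (median -1.56, adjusted p = 1.43e-06, and adjusted p = 0.558 with an estimated correlation). The erythropoietin receptor gene Epor fell by 4.21 on the log2 scale (SE 0.46), and Tspo2, of late red cell precursors, had -5.40 ± 0.89 (adjusted p = 0.0987). B cell genes were lower too, with 12 of 16 that fell adjusted over the list alone and 0 over all genes (median -2.78, adjusted p = 3.29e-11, and adjusted p = 0.533 with an estimated correlation). The CD20 gene Ms4a1 stood at 62.4 and 92.7 CPM in naive macrophages and 8.36 and 5.17 in TAM in contact, the surrogate light chain gene Igll1 had -3.02 ± 0.55, and the signalling genes Bank1 and Blk had -2.33 ± 0.29 and -2.17 ± 0.42.

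Several lists of inflammatory signalling were higher than in naive macrophages, though the list of inflammatory cytokines itself was not called (median 0.93, adjusted p = 0.276), with 4 of 17 genes that rose and 1 that fell adjusted over the list alone and 0 over all genes. Of 22 genes of the tumour necrosis factor and NF-kB response, 21 had positive values, with 1 that rose over all genes (Traf1) and 12 adjusted over the list alone (median 1.20, adjusted p = 3.23e-08, and adjusted p = 0.533 with an estimated correlation). The superoxide dismutase gene Sod2 had 1.29 ± 0.29 and Bcl3, a nuclear partner of NF-kB, 1.56 ± 0.34. In the interleukin 6 and STAT3 list 8 of 15 genes rose adjusted over the list alone and 0 over all genes (median 1.35, adjusted p = 1.01e-05, and adjusted p = 0.533 with an estimated correlation). The feedback inhibitor gene Socs3 stood at 162 and 567 CPM against 12.5 and 15.3 in naive macrophages, the transcription factor gene Cebpb had 3.61 ± 0.76, and this list held in fry (adjusted p = 0.0199). In the chemokine list 5 of 20 genes rose adjusted over the list alone and 0 over all genes (median 1.99, adjusted p = 0.000631, and adjusted p = 0.533 with an estimated correlation), with Ccl4 at 3.72 ± 0.61 and Ccl3 at 3.90 ± 0.77. Immediate early genes, which tissue dissociation also induces, moved with these lists. Of them 10 of 21 rose adjusted over the list alone and 0 over all genes (median 2.87, adjusted p = 1.14e-06, and adjusted p = 0.659 with an estimated correlation), with Fos at 5.04 ± 0.98, Junb at 3.66 ± 0.92 and Dusp1 at 3.997 ± 1.01. In the monocyte list 8 of 14 genes rose adjusted over the list alone and 0 over all genes (median 2.32, adjusted p = 0.000142, and adjusted p = 0.533 with an estimated correlation), with Ccr2 at 925 and 618 CPM against 79.7 and 109.9 and the fibronectin gene Fn1 at 2.77 ± 0.48. Camera called 18 of 44 lists, 12 higher and 6 lower in TAM in contact, 0 of them with an estimated correlation.

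The third comparison set TAM not in contact against naive macrophages. Several inflammatory and chemokine transcripts were at higher levels in TAM not in contact, and most marker transcripts of eosinophils, neutrophils and B cells at lower levels. The chemokine gene Ccl4 stood at 149 and 413 CPM against 8.32 and 5.30 (log2 fold change 5.49 ± 0.67 SE, n = 2 per group, adjusted p = 0.183). Rgs1, a regulator of G protein signalling, had 5.38 ± 0.59, Traf1 3.26 ± 0.35 and the matrix metalloprotease gene Mmp2 2.91 ± 0.34, each at an adjusted p of 0.183. Epx had -7.29 ± 0.81, Gfra4 -5.00 ± 0.54, and Spib, a transcription factor of B and dendritic cell lineages, -2.41 ± 0.28, also at 0.183. Sowahc (1.96 ± 0.25), Gpr132 (2.40 ± 0.30), Nupr1 (3.28 ± 0.47) and Arl5c (1.93 ± 0.27) had positive values, and Alox15 (-6.81 ± 0.78), Foxred2 (-2.29 ± 0.27), Card10 (-2.92 ± 0.37), the leukotriene receptor gene Ltb4r1 (-2.28 ± 0.33) and the chromatin organizer gene Satb1 (-2.25 ± 0.32) negative ones, at adjusted p-values of 0.183 to 0.219. None of these genes passed in edgeR's planned test. Of the genes behind the sort, Itgam had -1.74 ± 0.28 (adjusted p = 0.219), Adgre1 0.23 ± 0.51 (adjusted p = 0.883), Cd68 0.68 ± 0.59 (adjusted p = 0.655) and Ptprc 0.59 ± 0.50 (adjusted p = 0.64). With TAM not in contact replicate 1 left out, the last 3 turned to -0.46, -0.21 and -0.21, and without naive replicate 2 Adgre1 turned to -0.18.

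edgeR called 0 of 15522 genes between TAM not in contact and naive macrophages, with 2354 at an unadjusted p under 0.05. DESeq2 called 1269 genes (687 higher and 582 lower in TAM not in contact) and limma-voom called 0. Without TAM not in contact replicate 1 or 2 that group held 1 library and was assumed to vary like the others. Calls of such fits describe 1 library rather than the group.

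By list, 18 of 22 genes of the tumour necrosis factor and NF-kB response rose adjusted over the list alone and 0 over all genes (median 1.93, adjusted p = 3.99e-11, but adjusted p = 0.39 with an estimated correlation). Cd83, an activation marker, had 3.12 ± 0.62 and the NF-kB subunit gene Rel 2.27 ± 0.47. Of 20 chemokine genes, 8 rose adjusted over the list alone and 0 over all genes (median 3.28, adjusted p = 5.36e-08, and adjusted p = 0.39 with an estimated correlation), with Ccl3 at 3.63 ± 0.76. Of 17 inflammatory cytokine genes, 5 rose adjusted over the list alone and 0 over all genes (median 3.49, adjusted p = 0.000396, and adjusted p = 0.586 with an estimated correlation), with Il1b at 322 and 1735 CPM against 40.7 and 51.7. Immediate early genes moved with them, since 14 of 21 rose adjusted over the list alone and 0 over all genes (median 3.61, adjusted p = 4.38e-09, and adjusted p = 0.586 with an estimated correlation). Fos had 5.71 ± 1.01 and Atf3 5.86 ± 1.22. In the matrix and adhesion list 4 of 25 genes rose adjusted over the list alone and 0 over all genes (median 1.13, adjusted p = 0.000285, and adjusted p = 0.39 with an estimated correlation), with the matrix protein gene Sparc at 6.50 ± 1.08 and the fibronectin gene Fn1 at 2.41 ± 0.48. The stroma and endothelium list, which shares Col1a1, Col1a2, Col3a1 and Pecam1 with it, moved along, with 13 of 15 genes positive and 0 that passed over all genes or adjusted over the list alone (median 2.06, adjusted p = 0.033, and adjusted p = 0.586 with an estimated correlation). Its adjusted p was 0.483 without TAM not in contact replicate 2 and 0.0588 without naive replicate 2. The resident macrophage list was not called. Its median was 0.19, its mean -0.16 and its test pointed down (adjusted p = 0.827, and adjusted p = 0.929 with an estimated correlation), and 0 of 23 genes passed over all genes or adjusted over the list alone.

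Markers of other marrow cells also differed between TAM not in contact and naive macrophages. In the list of eosinophils, basophils and mast cells 10 of 16 genes fell adjusted over the list alone and 0 over all genes (median -3.54, adjusted p = 4.38e-09, and adjusted p = 0.39 with an estimated correlation). In the neutrophil list 11 of 17 fell adjusted over the list alone and 0 over all genes (median -1.95, adjusted p = 4.38e-09, and adjusted p = 0.494 with an estimated correlation), with the surface marker gene Ly6g at -2.95 ± 0.53, S100a8 at -2.26 ± 0.57 and Camp at -1.95 ± 0.50. In the B cell list 11 of 16 fell adjusted over the list alone and 0 over all genes (median -2.86, adjusted p = 1.39e-10, and adjusted p = 0.39 with an estimated correlation), with Ms4a1 at -3.78 ± 0.58, Igll1 at -4.99 ± 0.61, Vpreb1 at -4.84 ± 0.68 and Blk at -2.79 ± 0.43. Megakaryocyte and platelet genes were higher, with 10 of 15 that rose adjusted over the list alone and 0 over all genes (median 2.72, adjusted p = 5.36e-08, and adjusted p = 0.494 with an estimated correlation). Ppbp stood at 10.2 and 42.5 CPM against 1.07 and 0.485, and the platelet receptor gene Gp1ba had 3.30 ± 0.81. Of 23 plasma cell markers, all had positive values and 0 passed over all genes or adjusted over the list alone (median 2.17, adjusted p = 1.55e-05, and adjusted p = 0.586 with an estimated correlation), and without TAM not in contact replicate 2 the adjusted p was 0.102. Among them Derl3 had 4.16 ± 1.02, the elongation factor gene Eaf2 4.35 ± 1.14 and Sdc1 4.51 ± 1.504. Of 22 genes of the unfolded protein response, all had positive values and 0 passed over all genes or adjusted over the list alone (median 1.22, adjusted p = 3.65e-06, and adjusted p = 0.586 with an estimated correlation). All 7 measured transcripts of the mitochondrial genome had positive values, with 5 that rose adjusted over the list alone and 0 over all genes (median 1.28, adjusted p = 0.000835, and adjusted p = 0.586 with an estimated correlation), and without TAM not in contact replicate 2 the adjusted p was 0.0829. Camera called 23 of 44 lists, 18 higher and 5 lower, 0 of them with an estimated correlation, and fry called 3 (B cells, matrix and adhesion, and interleukin 6 and STAT3, each with an adjusted p of 0.0363).

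The study asked how many differential genes the macrophage subsets share. At an adjusted p of 0.05 edgeR gave no overlap to count, since a single comparison had calls. At an adjusted p of 0.1 it called 49 genes between the TAM groups and 145 for TAM in contact over naive, and 43 genes were shared in the same direction, 42 of them lower in TAM in contact. Independent lists of these sizes would share 0.323 genes, and 60 simulated sets of unchanged groups that shared the TAM in contact libraries gave at most 1. By DESeq2 558 genes were shared in the same direction and 12 in opposite directions between these 2 comparisons, against 78.1 for independent lists and at most 16 in 20 simulated sets. TAM in contact and TAM not in contact, each over naive, shared 299 DESeq2 genes in the same direction and 5 in opposite directions, against 53.9 for independent lists and at most 19 in simulation. Between TAM in contact over TAM not in contact and TAM not in contact over naive, 497 DESeq2 genes had opposite directions and 23 the same, against 72.1 opposite for independent lists and at most 15 in simulation. The groups hold 2 libraries each and cannot be split, so part of each excess may come from the shared libraries. Unchanged groups give false calls only, so the simulated overlaps do not show what shared libraries give for lists of the observed length. The edgeR log2 fold changes of the 2 comparisons over naive had a covariance of 1.16 across genes, against 0.414 in simulation (r = 0.449 against 0.502). With TAM in contact as the shared group the covariance was 1.33 against 0.408 (r = 0.5 against 0.496), and with TAM not in contact as the shared group -1.52 against -0.414 (r = -0.55 against -0.502). Genes are not independent replicates in these values.

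The series states that the macrophage subsets separate on principal components. Over the 500 most variable genes, the first component carried 51.3% of the variance, the second 28.8% and the third 13.7%. Naive libraries lay close together (distance 28.9 in log2 CPM units), as did those of TAM in contact (48.1). The libraries of TAM not in contact lay 109 apart, farther than replicate 1 lay from either library of TAM in contact (63.5 and 81.0). Mean distances between groups were 1.52 times those within groups. With 2 libraries a group no exact test of this separation can reach a p under 0.05.

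**Figure D2:**
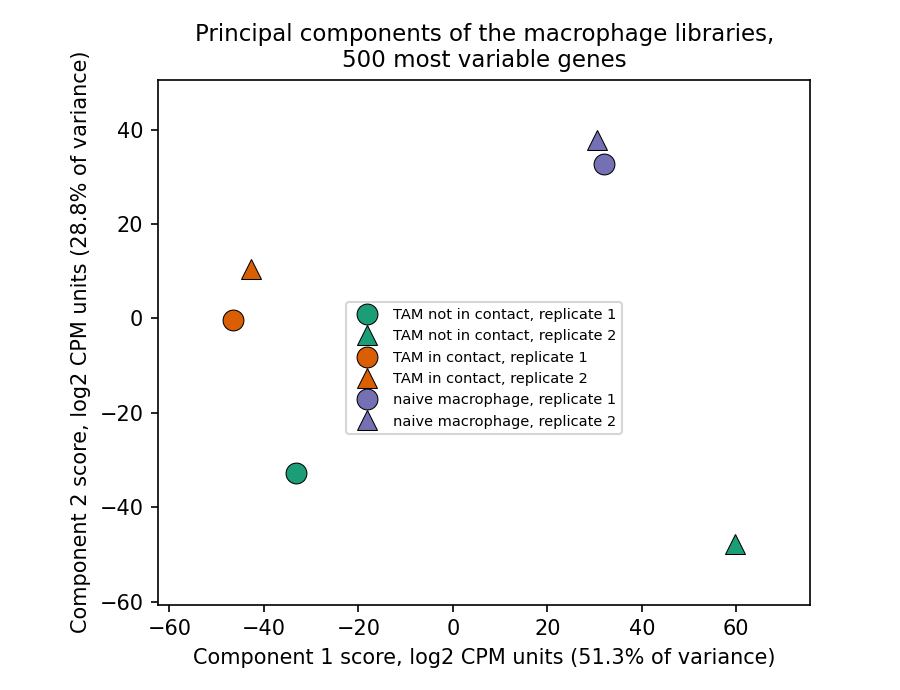
Scores of the 6 macrophage libraries on the first 2 principal components of log2 CPM (51.3% and 28.8% of the variance), 1 point per library. Naive macrophages and TAM in contact each form a close pair, and the libraries of TAM not in contact lie 109 apart over all components.

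The 2 plasma cell libraries carry the same label, which does not say whether either holds myeloma cells or polyclonal plasma cells, so they were not compared with each other. Immunoglobulin genes took 67.3% (95% Wilson interval 67.26% to 67.28%) and 70.4% (70.40% to 70.43%) of their counts. The kappa constant gene Igkc (chromosome 6, 70726435 to 70726966) alone held 19.6% and 25.8%, Igha 14.5% and 18.7%, and Ighm 11.1% and 4.01%. The J chain gene Jchain, which joins polymeric antibody, stood at 58241 and 79217 CPM, the transcription factor gene Xbp1 at 3886 and 4280, the endoplasmic reticulum protein gene Txndc5 at 3908 and 1980, and the CD138 gene Sdc1 at 914 and 289. Both libraries used many kappa variable segments, with at most 11.9% and 7.04% of kappa variable counts on any 1 of them. The leading heavy variable segment held 7.58% and 5.66% of heavy variable counts. These shares argue against a single clone as the main source of immunoglobulin counts in either library. They do not exclude a smaller share of myeloma cells, and counts of single segments are uncertain. Il6 had 3 and 1 counts and Tnf 1.80 and 1.83 CPM. Of the receptors through which plasma cells could receive these cytokines, Il6ra stood at 15.4 and 5.37 CPM, Il6st at 23.5 and 7.43, Tnfrsf1a at 9.85 and 5.29, and Tnfrsf1b at 14.04 and 8.01. Scaled to the counts outside immunoglobulin genes, these values were 47.0 and 18.2, 71.7 and 25.1, 30.1 and 17.9, and 42.9 and 27.1. The receptor gene Tnfrsf17, which encodes BCMA, stood at 58.1 and 92.5 CPM (178 and 313 on the second scale). These intervals cover counting error only.

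Plasma cell transcripts were present in the macrophage libraries, most of all in replicate 2 of TAM not in contact. Immunoglobulin genes took 9.13% of its counts (95% Wilson interval 9.12% to 9.14%), against 0.398% in replicate 1, 0.166% and 0.196% in TAM in contact, and 0.466% and 0.632% in naive macrophages. In that library Ighg2b (ENSMUSG00000076613.3, chromosome 12, 113302965 to 113307933, minus strand) made up 95.7% of heavy chain constant counts (interval 95.7% to 95.8%), and the segment Igkv5-48 made up 94.3% of kappa variable counts (94.3% to 94.4%). Sdc1 (ENSMUSG00000020592.14, chromosome 12, 8771323 to 8793715, plus strand) stood at 417 CPM there and at 3.73 to 10.8 in the other 5 macrophage libraries. Over TAM not in contact, TAM in contact had -5.42 ± 1.57 for Sdc1 (adjusted p = 0.205), -4.42 ± 1.09 for the B lineage coactivator gene Pou2af1 -4.78 ± 1.05 for the degradation factor gene Derl3, -5.10 ± 1.18 for Eaf2, -2.03 ± 0.44 for Mzb1, -5.52 ± 1.45 for Igkc and -6.20 ± 1.84 for Ighg2b. Over naive, TAM in contact had -0.91 ± 1.33 for Sdc1. Mzb1 was not raised in replicate 2 of TAM not in contact, where it stood at 10.98 CPM, against 21.6 in replicate 1 and 14.02 and 14.7 in naive macrophages. Of 23 plasma cell markers, 11 fell adjusted over the list alone and 0 over all genes (median -2.30, adjusted p = 3.34e-06, and adjusted p = 0.569 with an estimated correlation). Of 11 immunoglobulin constant genes, 4 fell adjusted over the list alone and 0 over all genes (median -4.08, adjusted p = 0.026, and adjusted p = 0.629 with an estimated correlation). Without TAM not in contact replicate 2 the adjusted p of the constant genes was 0.158, and without TAM in contact replicate 1 it was 0.115. Constant and variable immunoglobulin genes share near-identical stretches, so counts of single segments are uncertain.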

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

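All results in this part were picked out by rules fixed before the data were examined, and no test was chosen for them after their values were seen. A first result comes from a signal outside the comparisons. The table of the plasma cell libraries has an entry for EGFP, the reporter of the myeloma cells, with 20 counts in replicate 1 and 9 counts in replicate 2. A count of 0 allows up to 3 counts, and both values lie above it. At 81792139 and 38343783 total counts these are few reads, and neither library can be named myeloma or polyclonal from them. The macrophage table has no such entry.

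A second set of results comes from genes whose 2 libraries of TAM in contact lay on 1 side of both naive libraries and whose 2 libraries of TAM not in contact lay on the other. Of the 103 genes named in the text, 11 did so. Many of the 103 were named for small p-values or non-overlapping libraries in these same comparisons. Their share therefore cannot be set against the share over all genes. The log2 fold change of TAM in contact over TAM not in contact was -5.20 for Plpp3, -4.18 for Pxdc1, -4.42 for Gdpd1, 2.31 for Gpr141, -6.67 for Ppbp, -1.93 for Ctsl, -6.92 for Il1a, -4.78 for Derl3, -5.10 for Eaf2, -6.20 for Ighg2b and -3.02 for Mmp2. Plpp3, a lipid phosphatase gene, stood at 48.0 and 60.0 CPM in TAM not in contact, 1.06 and 1.83 in TAM in contact, and 34.5 and 18.8 in naive macrophages. Mmp2, a matrix metalloprotease gene, stood at 41.9 and 28.6, 4.76 and 3.89, and 5.08 and 5.30 CPM. None of these genes passed in edgeR's planned test between the TAM groups, which called 0 genes, with 2653 at an unadjusted p under 0.05. DESeq2 called all 11 among its 1619, and limma-voom called 0. With the mouse number as a block edgeR called 59 genes, Plpp3, Pxdc1 and Gdpd1 among them, but the libraries numbered mouse 2 are not from 1 animal. Whether the 2 differences from naive differ from each other was not tested beyond that comparison. Over all 15522 genes 688 lay on opposite sides (4.43%, where chance gives 2.22%), 351 with TAM in contact above naive and 337 with TAM in contact below. Derl3, Eaf2 and Ighg2b are plasma cell genes, and their high values in TAM not in contact come largely from replicate 2 (143, 62.2 and 51674 CPM, against 16.4, 4.81 and 806 in replicate 1). The margin to naive was small for Mmp2, and for Derl3, at 3.78 CPM in TAM in contact replicate 1 against 3.82 in naive replicate 1.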

How the results depend on the processing

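The alternatives were fixed before the data were examined, except the bias-adjusted quasi-dispersions, which were chosen after the data were seen. Numbers below are in the order TAM in contact over TAM not in contact, TAM in contact over naive, TAM not in contact over naive. Against 0, 34 and 0 genes called by edgeR (2653, 2270 and 2354 at an unadjusted p under 0.05), DESeq2 called 1619, 1230 and 1269, limma-voom 0, 0 and 0, RLE size factors 0, 22 and 0, no filter on low counts 1871, 1437 and 1548, a stricter filter 27, 52 and 0, fits on the 2 groups compared 0, 664 and 0, and removal of immunoglobulin and plasma cell genes 0, 22 and 0. Bias-adjusted quasi-dispersions gave 22, 56 and 0. This option was not specified in advance, and its counts were seen beside those of the default. With each library left out in turn the counts ranged from 0 to 1510, 0 to 534 and 0 to 477. A group left with 1 library is assumed there to vary like the others. The 1510, 534 and 477 arose without TAM not in contact replicate 1, and the second comparison fell to 0 without any 1 of its own 4 libraries. The labels number the TAM libraries by mouse, and this number as a block gave 59, 187 and 0 genes (13, 15 and 0 named genes gained a call) and changed no list call. Deviations from the group means of libraries with 1 number correlated at 0.152, and the sex-linked genes show that those of mouse 2 are not from 1 animal.

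Gene lists called were 19, 18 and 23. An estimated correlation gave 0, 0 and 0, and fry 1, 1 and 3. Calls shared by TAM in contact over TAM not in contact and TAM in contact over naive were 0, then 43 at an adjusted p of 0.1 and 558 by DESeq2. DESeq2 shared 299 between the comparisons over naive and 23 between TAM in contact over TAM not in contact and TAM not in contact over naive. The ratio of distances between and within groups was 1.52, then 1.41 with 2000 genes and 1.33 with all genes past the filter.

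The 18 called genes whose values over naive the text gives kept their direction in 270 of 270 alternatives. The libraries of the groups compared did not overlap for any of these genes, so a kept direction was largely fixed in advance. Their calls did not all hold, and limma-voom kept none of them. Over all named genes 1687 values kept direction and side of the threshold, 466 gained a call, 94 lost it and 13 turned. Leaving out 1 library moved TAM in contact over TAM not in contact from -3.26 to between -4.21 and 0.95 for Tnf and from -0.77 to between -1.32 and 0.084 for Cd68. For TAM in contact over naive, Il6 moved from 0.33 to between -1.11 and 1.04 (also -0.08), Adgre1 from -0.53 to between -0.93 and 0.035, Itgam from -0.21 to between -0.39 and 0.029, and Cd68 from -0.09 to between -0.51 and 0.53 (also 0.14, and 0.019 with limma-voom). For TAM not in contact over naive, Adgre1 moved from 0.23 to between -0.46 and 0.78 (also -0.18), Ptprc from 0.59 to between -0.21 and 1.09, and Cd68 from 0.68 to between -0.21 and 1.29. Of list results 442 stayed, 155 lost a call and 3 turned. In medians of log2 CPM differences, which differ from the fitted medians of the report, type I interferon moved from 0.90 to between -0.22 and 1.72 for TAM in contact over naive and from 0.74 to between -0.26 and 1.49 for TAM not in contact over naive, and lysosome in the last comparison from 0.58 to between -0.033 and 1.04. The cause of these changes was not tested. A count of 0 allows 0.064 to 0.104 CPM in a macrophage library.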

Other observations

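All tests of explanations in this part were chosen after the result they address was seen, while the gene lists themselves were fixed earlier. Class I antigen presentation genes lay higher in both TAM groups than in naive macrophages. The class I gene H2-Q7, which has close paralogs that share reads, stood at 68.5 and 58.8 CPM in TAM in contact and 15.9 and 19.2 in naive macrophages (log2 fold change 2.01 ± 0.34, n = 2 per group, adjusted p = 0.104), and its value for TAM not in contact was 2.31 ± 0.35 (adjusted p = 0.219). Psmb8, of the immunoproteasome, had 1.29 ± 0.39 for TAM in contact over naive (adjusted p = 0.251). Of 16 class I genes, 2 rose adjusted over the list alone and 0 over all genes in TAM in contact (median 1.10, adjusted p = 1.83e-07, but adjusted p = 0.533 with an estimated correlation). In TAM not in contact 2 rose adjusted over the list alone and 0 over all genes (median 0.94, adjusted p = 1.23e-06, and adjusted p = 0.39 with an estimated correlation). The class II list was called in TAM in contact, with 0 of 12 that passed over all genes or adjusted over the list alone (median 1.46, adjusted p = 0.00901, and adjusted p = 0.72 with an estimated correlation), and without TAM in contact replicate 1 the adjusted p was 0.164. In TAM not in contact the class II list was not called (median 1.32, adjusted p = 0.373), with 1 gene that fell adjusted over the list alone and 0 over all genes, and between the TAM groups it was not called either (adjusted p = 0.0837). The lists of dendritic cells and of T and NK cells were also called in TAM in contact over naive. Of 14 dendritic cell genes 13 had positive values, and 1 rose adjusted over the list alone and 0 over all genes (median 0.74, adjusted p = 0.0472, and adjusted p = 0.688 with an estimated correlation). Of 18 genes of T and NK cells 16 had positive values, and 0 passed over all genes or adjusted over the list alone (median 1.20, adjusted p = 0.0167, and adjusted p = 0.841 with an estimated correlation). Without TAM in contact replicate 1 these calls were lost (adjusted p = 0.77 and 0.939), and the dendritic cell call also without naive replicate 2 (adjusted p = 0.128). Cd274, the gene of the checkpoint ligand PD-L1, stood at 217 and 774 CPM in TAM not in contact, 189 and 251 in TAM in contact, and 34.4 and 26.4 in naive macrophages, with 4.15 ± 0.66 for TAM not in contact over naive (adjusted p = 0.219).

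Interferon genes had positive values against naive in both TAM groups, through some libraries more than others. The guanylate-binding protein gene Gbp2 had 2.44 ± 0.58 for TAM in contact (adjusted p = 0.18) and 2.36 ± 0.58 for TAM not in contact (adjusted p = 0.224), and the nucleic acid sensor gene Zbp1 2.72 ± 0.52 (adjusted p = 0.129) and 2.09 ± 0.51 (adjusted p = 0.224). With the mouse number as a block Gbp2 and Zbp1 passed for TAM in contact over naive, but the libraries numbered mouse 2 are not from 1 animal. Of 19 interferon gamma genes, 0 passed over all genes or adjusted over the list alone (median 1.11, adjusted p = 0.00066, and adjusted p = 0.659 with an estimated correlation, for TAM in contact; 1.17, adjusted p = 0.000742, and adjusted p = 0.591 with an estimated correlation, for TAM not in contact). The adjusted p of that list was 0.19 without TAM in contact replicate 1 and 0.241 without TAM not in contact replicate 1. Of 28 type I interferon genes, 0 passed over all genes or adjusted over the list alone in TAM in contact (median 1.11, adjusted p = 0.0194, and adjusted p = 0.879 with an estimated correlation). Without TAM in contact replicate 1 that list turned down (adjusted p = 0.373), and without naive replicate 2 its adjusted p was 0.0749. In TAM not in contact 0 passed over all genes or adjusted over the list alone (median 0.95, adjusted p = 0.0125, and adjusted p = 0.799 with an estimated correlation), and without TAM not in contact replicate 1 the list turned down (adjusted p = 0.985). For 25 nuclear genes of oxidative phosphorylation in TAM in contact the median was 0.46, with 0 that passed over all genes or adjusted over the list alone (adjusted p = 0.00111, and adjusted p = 0.67 with an estimated correlation).

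Replicate 2 of TAM not in contact held 9.13% immunoglobulin counts, with 94.3% of kappa variable counts on Igkv5-48. A swap of labels of replicate 2 alone with 1 library of TAM in contact is argued against by the resident macrophage list. Its median log2 ratio to TAM not in contact replicate 1 was -2.17 and -3.93 in the libraries of TAM in contact and -0.17 in replicate 2. The list takes the label of replicate 1 as right. An exchange of labels between the 2 TAM groups would divide the libraries in the same way and was not tested. Other values bear on a swap without settling it. In principal component distances replicate 1 lay nearer to TAM in contact (63.5 and 81.0) than to replicate 2 (109). Replicate 2 lay farther from TAM in contact (119 and 120) than from replicate 1. Immunoglobulin counts were higher in replicate 2, and in replicate 1 (0.398%), than in TAM in contact (0.166% and 0.196%). The shares in TAM in contact lay below those of naive macrophages (0.466% and 0.632%). The libraries numbered mouse 2 are not from 1 animal. RNA of plasma cells with the profile of the plasma cell libraries was tested at a predicted share of 12.8%. The median ratio of observed to predicted excess was 1.51 over the only 4 genes that qualified (quartiles 0.273 and 3.32). That median met the bound set for this explanation. A minimum of 10 genes was added after the 4 were seen, so the test is taken to decide nothing. Heavy chain constant genes argue against this profile as the main source. Ighg2b stood at 51674 CPM in replicate 2, above the 48488 and 38095 of the plasma cell libraries themselves. Igha stood at 1161 CPM, against 144532 and 186795, and Ighm at 735, below the 1518 of replicate 1. Igkc, at 23693 CPM against 195668 and 257723, does not argue against it. RNA of a myeloma clone may be the source. Polyclonal plasma cells as the main source of the immunoglobulin counts of replicate 2 are argued against. Its leading heavy variable segment, Ighv1-26, held 88.5% of heavy variable counts, and 2 segments exceeded 1%. In the plasma cell libraries the leading heavy segment held 7.58% and 5.66%, and 33 and 36 segments exceeded 1%. Ighg2b held 95.7% of heavy chain constant counts in replicate 2, against 13.4% and 12.6%. The kappa share of 94.3% is the pattern itself and was not counted, and counts of single segments are uncertain.

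Resident macrophage genes were lower in TAM in contact than in naive macrophages. A lower share of macrophages that raised the markers of every other cell type alike was not seen. B cell genes had a median of -2.78, with 12 members that fell adjusted over the list alone and 0 over all genes. The B cell list had an adjusted p of 0.533 in camera with an estimated correlation. In the monocyte list 8 members rose adjusted over the list alone and 0 over all genes. B cell genes also fell in TAM not in contact over naive (median -2.86), where the resident list had a median of 0.19. Their fall therefore cannot decide on the share of macrophages, and dilution by some cell types only would not raise every list. More eosinophils or neutrophils than in the naive libraries is argued against by medians of -0.79 and -0.68, with 0 members that rose over all genes or adjusted over the list alone. Monocyte-derived macrophages in place of resident ones may account for it, since the monocyte list had a median of 2.32, but its call was lost with an estimated correlation (adjusted p = 0.533) and whole monocytes, which the sort for F4/80 high and CD11b low cells should remove, would raise the same genes.

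Tnf stood at 909 CPM in replicate 2 of TAM not in contact. RNA of plasma cells with the profile of the plasma cell libraries is argued against, since these held at most 1.83 CPM of Tnf (6.17 when scaled to the counts outside immunoglobulin genes). Induction of immediate early genes during tissue handling could contribute, since 15 of 21 such genes were higher than in TAM in contact replicate 2 (median log2 ratio 1.19, quartiles -0.16 and 2.29, against 3.78 for Tnf). Against the other 4 macrophage libraries that median was 2.77, 2.52, 4.17 and 4.14. Activation within the marrow would raise the same genes and was not tested apart from handling, and a myeloma clone unlike the plasma cell libraries was not tested.

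The segment Igkv5-48 led kappa variable counts in all 6 macrophage libraries, those of naive mice included, with 51.8% in TAM not in contact replicate 1, 47.0% and 84.3% in TAM in contact, and 20.6% and 18.2% in naive macrophages. It took 1.10% and 0.689% in the plasma cell libraries, where other segments led. Its counts were 8667 and 291137 in TAM not in contact. They were 1879 and 4615 in TAM in contact, and 4484 and 3060 in naive macrophages. These values do not tell which cells or libraries the reads came from, and their source was not tested. Counts of the X-linked RNA Xist and of 4 Y-linked genes gave 0 and 8006 in TAM in contact replicate 2, against 777 to 2521 for Xist and at most 26 for the Y-linked genes in the other 5 macrophage libraries. TAM in contact and TAM not in contact that carry mouse number 2 are therefore not from 1 and the same animal alone. The plasma cell libraries had 4173 and 1197 Y-linked counts and 16 and 12 counts of Xist.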
